A study of Nitrosomonas europaea and Nitrobacter winogradskyi and Nitrobacter winogradskyi
Nitrosomonas europaea with 9 samples.

How the data were processed

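RNA was measured in 9 chemostat samples: 3 single cultures of *Nitrosomonas europaea*, 3 single cultures of *Nitrobacter winogradskyi* and 3 co-cultures. The substrate of the *N. winogradskyi* single cultures was taken as nitrite from the sample labels, where the series description says nitrate. Ribosomal RNA was reduced with a bacterial mRNA enrichment kit, and the replicates are biological replicates, per the labels' protocols. Reads were aligned with Bowtie and Bowtie2 (version 2.1.0), per the submitters' processing notes; the counting tool and its settings are not given in the sources used here. The deposited tables give, per species and gene, a whole-number pseudo count for each library, the authors' log2 fold change and the authors' p-value, per the file headers. The headers call the counts unique, and the handling of reads that match several genes is not given in the sources used here. The step that produced the pseudo counts is not given in the sources used here. The totals were nearly equal within a species (1312629 to 1313564 and 42913 to 43811). No whole number from 0 to 30 was missing. The variance over the mean of genes with mean counts of 2 to 16 was 1.19 to 2.43 within groups. The deposited pseudo counts were therefore handled as counts. Thinning to a common depth was assumed, since these values cannot tell it from another adjustment with rounding. The original depth of each library is unknown. Because the totals are nearly equal within each species, the share of co-culture reads from each species has no value here. The deposited log2 fold changes equal the log2 ratio of the summed pseudo counts to within 5.3e-15, and the test behind the authors' deposited p-values is not stated in the headers. In the *N. winogradskyi* table, 55 entries carried neither a gene identifier nor counts and were left out.

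Each species was tested on its own genes with edgeR (version 4.0.16, R 4.3.3): filtering by expression, trimmed-mean (TMM) scaling over that species' genes, a robust quasi-likelihood fit, and a comparison of 3 co-cultures with 3 single cultures, with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Levels are TMM-normalized CPM. Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and again with an estimated correlation, over lists with at least 3 tested members. The lists were defined by patterns on the annotation and by locus tags, and include ribosomal proteins, respiratory complexes, carbon fixation, nitrogen oxide metabolism, ammonia or nitrite oxidation, stress, iron uptake, motility and efflux. List means and medians are those of the edgeR fold changes.

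The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the lists without pattern mismatches, the leave-one-out fits of the lists and those tests of explanations that are said to have been chosen later. Named genes were, per species, the 8 largest increases and the 8 largest decreases among genes with adjusted p under 0.05, no overlap between groups, a mean log2 CPM of at least 4 and an annotated product or symbol, together with fixed key genes of ammonia oxidation, nitrite oxidation, nitrogen oxides, carbon fixation, ammonium transport and quorum sensing, and up to 4 members with the smallest p in each list described. A few other genes are named and said to have been chosen after their values were seen.

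The procedure was tested on simulated counts with 200 genes changed by 2-fold or 4-fold, in 5 simulations per species. Of the calls, 5.44% in *N. europaea* and 3.11% in *N. winogradskyi* were unchanged genes. The simulated noise was drawn independently for each gene and library. It lacked the shared shifts of neighbouring genes and of whole libraries seen in these data, so these shares need not hold for them. The alternatives were RLE scaling, total-count scaling, no low-count filter, a mean of at least 50 counts, DESeq2 (version 1.42.0), limma-voom, the replicate number as a block, each library left out in turn, thinning to the smallest total and an adjusted p under 0.01. Library pairs within each group were compared by a chi-square test over genes with a summed count of at least 10. The closest pairs, single cultures 2 and 3 of each species, still differed beyond counting noise (chi-square per degree of freedom 1.77 and 1.37). That argues only against copies that differ by counting noise. Repeats of 1 culture can differ by more, so the test cannot exclude them. All libraries were kept as the biological replicates that the labels' protocols name. Intervals for ratios of summed counts are exact (Clopper-Pearson, 95%) if the pseudo counts behave as counts, and cover counting error only. Tables and figures were made with Python 3.11.15 and its packages numpy, pandas, scipy and matplotlib. Applying the Benjamini-Hochberg adjustment to the p-values in the authors' deposited table gave 447 *N. europaea* genes and 92 *N. winogradskyi* genes under 0.05. Of the 367 and 28 edgeR calls, 312 and 26 were among them, all in the same direction. The reverse overlap was smaller in *N. winogradskyi*, where 44 of the 92 genes were not tested by edgeR, against 3 of the 447 in *N. europaea*. The 92 were 30 higher and 62 lower, against 21 higher and 7 lower by edgeR. The 447 were 216 higher and 231 lower, against 213 and 154.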

Results

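Transcripts of *Nitrosomonas europaea*, a bacterium that oxidizes ammonia to nitrite, and of *Nitrobacter winogradskyi*, a bacterium that oxidizes nitrite to nitrate, were counted by RNA sequencing in continuous-flow cultures (chemostats) run at a dilution rate of 0.008 per hour. *N. europaea* grew alone on 60 mM ammonium, *N. winogradskyi* grew alone on 60 mM nitrite per the sample labels (the series description names nitrate instead), and both grew together on 60 mM ammonium. Each of these groups had 3 biological replicates, which makes 9 samples. The deposited values were whole-number pseudo counts per gene, with nearly equal totals within each species. The 6 libraries with *N. europaea* counts held 1312629 to 1313564 counts over 2557 genes, with a median count of 153. The 6 libraries with *N. winogradskyi* counts held 42913 to 43811 counts over 3143 genes, with a median count of 5. Simulated counts at these depths had noise drawn independently for each gene and library, unlike the deposited counts. On them, edgeR's quasi-likelihood test recovered 71.6% of the 2-fold changes and 98.4% of the 4-fold changes in *N. europaea*. In *N. winogradskyi* it recovered 10% of the 2-fold and 52.8% of the 4-fold changes, so a gene that did not pass there can still have changed by several fold. All fold changes compare the co-culture with the single culture of the same species, with n = 3 in each group, and an error given after ± is the standard error of a log2 fold change or the SD of a level. Coordinates were not used here, and genes are named by the locus tags and symbols of the deposited tables.

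The first comparison asks how *N. europaea* expressed its genes beside a nitrite oxidizer. The nirK cluster was far lower in co-culture. NE0924 (nirK/aniA), which encodes a copper nitrite reductase, went from 7343 ± 1345 normalized CPM (counts scaled to a common library total, SD, n = 3) in single culture to 63.6 ± 11.2 CPM in co-culture, a log2 fold change of -6.85 ± 0.36 (edgeR adjusted p = 5.93e-06). Its neighbours NE0925 (ncgC), NE0926 (ncgB) and NE0927 (ncgA), annotated as cytochrome and copper oxidase genes of the same cluster, had log2 fold changes of -9.43 ± 0.38, -8.67 ± 0.42 and -9.63 ± 0.47. Summed over 3 libraries, NE0927 had 28107 counts in single culture and 33 in co-culture, a ratio of 852 (95% exact interval for counting error 606 to 1238). Every co-culture library lay below every single-culture library for all 4 genes.

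**Figure D1:**
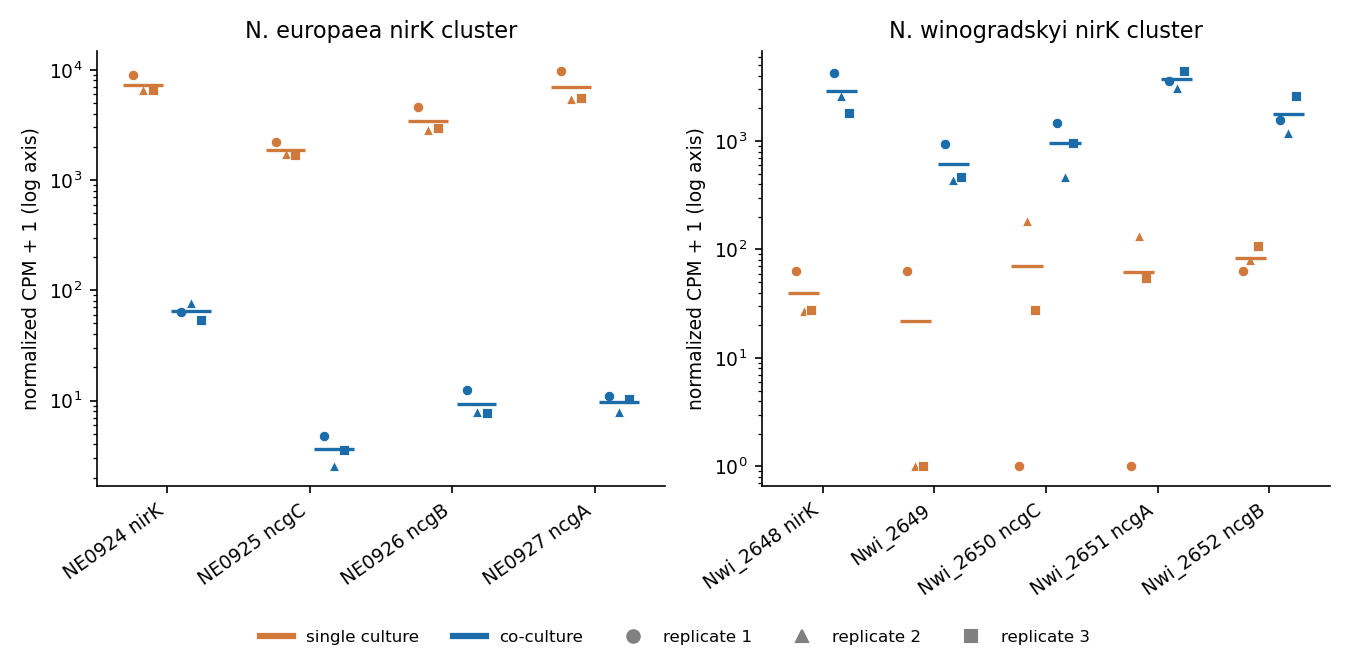
Normalized CPM plus 1 on a log axis for the genes of the nirK clusters of *N. europaea* (left) and *N. winogradskyi* (right), with 1 point per library, marker shapes for replicates, orange for single cultures, blue for co-cultures and horizontal lines at the group means. The 4 *N. europaea* genes lie lower in all 3 co-cultures and the 5 *N. winogradskyi* genes lie higher in all 3 co-cultures than in the single cultures of the same species.

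Among named *N. europaea* genes, NE0683 (nor, coxA2), annotated as subunit I of a cytochrome c oxidase, had the largest increase and rose by 1.97 ± 0.44 on the log2 scale (edgeR adjusted p = 0.0191), and its neighbour NE0684 (norS, coxB), chosen after its values were seen, rose by 1.74 ± 0.51. The ammonium transporter NE0448 (amtB) rose by 1.91 ± 0.28, from 176 ± 6.54 to 660 ± 248 CPM (edgeR adjusted p = 0.00506). The RNA polymerase subunit gene NE2046 (rpoB) rose by 1.89 ± 0.33 and the protein translocation gene NE0421 (secY) by 1.83 ± 0.30. NE1009, annotated as a D-lactate dehydrogenase, rose by 1.84 ± 0.28 and the membrane protein gene NE1011, which lies 2 loci further on, by 1.80 ± 0.43. Below the nirK cluster, the largest decreases under the same rule were smaller. They were NE0231 (-1.84 ± 0.39), the LysR-family regulator NE1544 (-1.80 ± 0.22), the RNA helicase gene NE1807 (-1.61 ± 0.37) and NE1921 (cbbL). NE1921 encodes the large subunit of RuBisCO, the enzyme that fixes carbon dioxide, and went from 36136 ± 1346 to 11859 ± 5882 CPM, a log2 fold change of -1.61 ± 0.41 (edgeR adjusted p = 0.0316). Leaving out any library other than co-culture 3 ended the call of NE1921, with adjusted p from 0.0768 to 0.118. Leaving out any library of the single culture ended the calls of NE0683 (adjusted p from 0.0621 to 0.105), NE1011 (0.0879 to 0.0999) and NE1807 (0.0738 to 0.0788), and so did co-culture 1 for NE1807 (0.0840). Without co-culture 3 the log2 fold changes of NE1011 and NE0684 were 1.09 and 1.07. NE0231 lost its call without co-culture 1 or without single culture 1 or 3 (0.0637, 0.0603 and 0.0539). Without single cultures 2 and 3 the adjusted p was 0.0677 and 0.0625 for NE2046 and 0.0675 and 0.0578 for NE0421.

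Genes of ammonia oxidation itself were mostly not called. Of the 8 tested members of the ammonia oxidation list, 1 rose and 7 did not pass, and the count adjusted over the list alone was also 1. The list as a whole did not pass (camera adjusted p = 0.872, downward), with a mean of 0.01, which total-count scaling turned to -0.08, and a median of -0.13. The member that rose was NE0143, the red copper protein nitrosocyanin, at 1.13 ± 0.28 (edgeR adjusted p = 0.0271), and this call was lost without co-culture 1 (adjusted p = 0.0542) and without each single culture (0.0765, 0.148 and 0.156). The main ammonia monooxygenase genes NE0945 (amoC1), NE0944 (amoA1) and NE0943 (amoB1) had log2 fold changes of -0.12 ± 0.51, -0.53 ± 0.59 and -0.23 ± 0.57 and were not called. Co-culture 3 stood apart there: NE0945 had 42124 counts in it, against 163796 and 158210 in co-cultures 1 and 2 and 137313 to 141242 in the single cultures. Without co-culture 3 the sign turned for NE0945 (0.27) and NE0943 (0.21), again without a call. NE2044 (hao1), for hydroxylamine oxidoreductase, had -0.44 ± 0.27, NE2064 (amoC) 0.07 ± 0.42, NE1411 (amoC3) -0.14 ± 0.24 and NE2004 (norB) -0.21 ± 0.21, none of them called. NE2062, NE2063 and NE0962, further copies of amoB, amoA and hao, were listed at 0 in all 6 libraries and NE2339 (hao3) at a single count. The handling of reads that match several copies is not given in the sources used here, so a count of 0 does not show that a copy was silent.

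**Figure D2:**
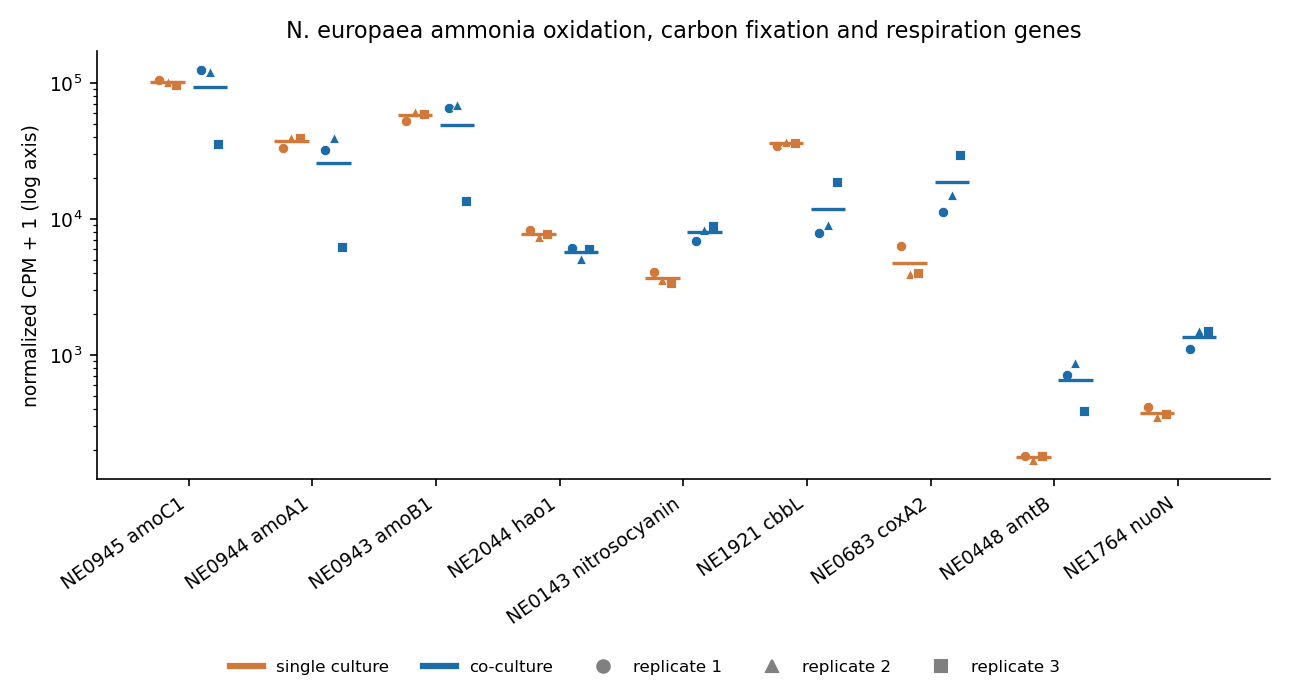
Normalized CPM plus 1 on a log axis for 9 *N. europaea* genes of ammonia oxidation, carbon fixation, respiration and ammonium transport, with 1 point per library, marker shapes for replicates and lines at the group means. Co-culture 3 (blue squares) lies below the other co-cultures for amoC1, amoA1 and amoB1, while amtB and nuoN lie higher and cbbL lower in all 3 co-cultures.

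Several gene lists of growth and energy metabolism had members that rose in *N. europaea*, though most members did not pass. Of 56 ribosomal protein genes, 24 rose and 32 did not pass (29 rose when adjusted over the list alone), with a mean log2 fold change of 0.89 ± 0.60 (SD over genes). NE0427 (rplQ) rose by 1.71 ± 0.26, NE0410 (rpsQ) by 1.69 ± 0.28, NE0409 (rpmC) by 1.54 ± 0.24 and NE2048 (rplJ) by 1.54 ± 0.28. The list passed camera with its preset correlation (adjusted p = 1.54e-08) and not otherwise (adjusted p = 0.682 with an estimated correlation). Of 21 genes of the NADH dehydrogenase list, 9 rose and 12 did not pass, and 11 rose and 1 fell when adjusted over the list alone. NE1764 (nuoN), NE1767 (nuoK) and NE1768 (nuoJ) rose by 1.86 ± 0.23, 1.85 ± 0.23 and 1.73 ± 0.19. The camera adjusted p was 0.000414 (adjusted p = 0.196 with an estimated correlation). Of 10 ATP synthase genes, 3 rose and 7 did not pass (6 rose when adjusted over the list alone), namely NE0207 (atpC, 1.47 ± 0.29), NE0206 (atpD, 1.38 ± 0.31) and NE0205 (atpG, 1.44 ± 0.34), while NE0203 (atpH) had 1.33 ± 0.42 without a call. That list had a camera adjusted p of 0.014 (adjusted p = 0.682 with an estimated correlation).

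Of 16 genes for chaperones and heat shock proteins, 2 rose and 14 did not pass (5 rose when adjusted over the list alone). NE1948 (dnaJ) rose by 1.43 ± 0.32 and the HSP20-family gene NE2074 by 1.12 ± 0.21, while NE1949 (dnaK, 1.09 ± 0.35) and NE1950 (grpE, 1.28 ± 0.41) were not called. Of 28 tested genes for cytochromes c and their maturation, 4 rose and 24 did not pass, and 5 rose and 2 fell when adjusted over the list alone. The 4 that rose belong to cytochrome c assembly: NE0770 (ccmH, 1.06 ± 0.19), NE0771 (cycH, 1.17 ± 0.24), NE0769 (ccmG/DsbE, 0.87 ± 0.19) and NE0767 (ccmE, 0.89 ± 0.23). Their camera adjusted p-values were 0.014 for chaperones and 0.0403 for cytochromes c (both adjusted p = 0.682 with an estimated correlation). Co-culture 3 moved with several of these groups. The mean log2 CPM of the ribosomal protein genes was 10.68 in co-culture 3 against 9.70 and 9.51 in co-cultures 1 and 2 and 9.06 to 9.40 in the single cultures, and that of the ATP synthase genes was 10.86 against 9.95 and 9.57. Without co-culture 3 the mean log2 fold change on the voom scale went from 0.78 to 0.42 for ribosomal proteins, from 0.81 to 0.43 for ATP synthase and from 0.38 to 0.24 for cytochromes c. Without that library the ATP synthase list (adjusted p = 0.0883) and the cytochrome c list (adjusted p = 0.0954) were no longer called, and without single culture 3 the cytochrome c list was not (adjusted p = 0.0528).

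Fewer lists fell. Of 89 genes for iron uptake and TonB-dependent receptors, 9 fell, 1 rose and 79 did not pass (8 fell and 1 rose when adjusted over the list alone), with a mean of -0.25 ± 0.52. Those that fell included the sigma factor gene NE1079 (fecI, -1.41 ± 0.21), the transport gene NE1211 (-1.18 ± 0.21), annotated for the siderophore enterobactin, and the sensor gene NE1095 (fecR, -1.01 ± 0.19). The member that rose, NE0772 (bcp, 2.84-fold), is annotated as a peroxiredoxin. The camera adjusted p was 0.00447 (adjusted p = 0.712 with an estimated correlation), and the list was not called without co-culture 3 (adjusted p = 0.0958, with a voom-scale mean of -0.15 against -0.27), whose mean log2 CPM of 5.62 lay below the 5.93 and 6.02 of the other co-cultures. The nitrogen oxide metabolism list (camera adjusted p = 5.30e-05, and adjusted p = 0.196 with an estimated correlation) held 10 genes, of which 4 fell, 1 rose and 5 did not pass, with the same counts when adjusted over the list alone. The 4 that fell were the nirK cluster, which set the mean at -3.40 beside a median of -0.31.

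The calls of single list members rested on few libraries. Of 19 called members named for the 7 lists and not under another part of the naming rule, 9 kept their call without single culture 1, 4 without single culture 2 and 4 without single culture 3, against 17 without co-culture 1 and 19 without co-culture 2 or 3. Those that kept it without each single culture were NE0409 (rpmC), NE1768 (nuoJ), NE1769 (nuoI) and NE1079 (fecI). With total-count scaling, DESeq2 and limma-voom all 19 kept it.

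**Figure D3:**
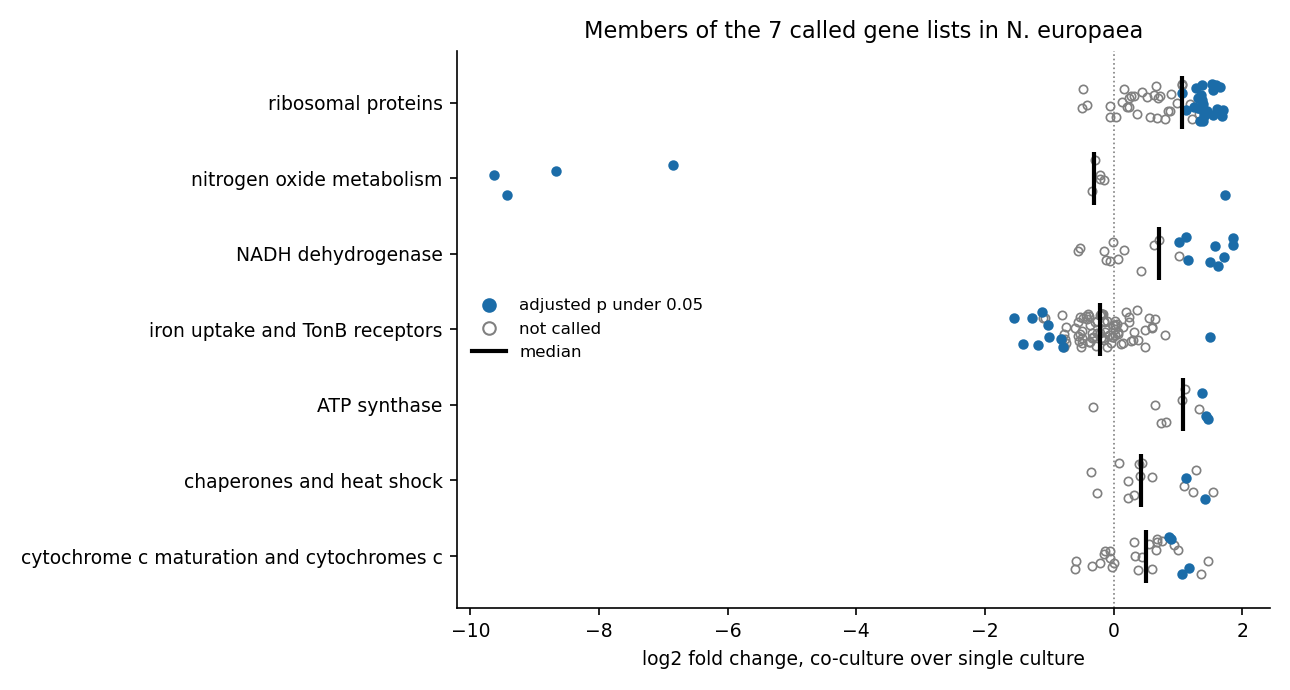
Log2 fold changes (co-culture over single culture) of the tested members of the 7 *N. europaea* gene lists that passed camera with its preset correlation, with 1 point per gene, filled where the gene passed edgeR's adjusted threshold of 0.05 and open where it did not, and black bars at the list medians. Ribosomal protein genes lie mostly above 0 (median 1.06), and the 4 nirK cluster genes lie far below the other members of the nitrogen oxide list (median -0.31).

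Over all 2376 *N. europaea* genes tested, 213 were higher and 154 lower in co-culture at an edgeR adjusted p under 0.05, and 811 had an unadjusted p under 0.05. The change was at least 2-fold for 120 of the higher and 66 of the lower genes. With scaling by total counts the split was 162 higher and 199 lower, since that scaling moved the median log2 fold change of all genes by -0.11. The 7 called lists kept the sign of their mean and median under each scaling. The count rested on the libraries: it was 209 without co-culture 1, 633 without co-culture 3, and 103, 54 and 45 without single cultures 1, 2 and 3. The groups did not overlap in 972 genes, 40.9% of those tested, where chance gives 10%.

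The second comparison asks how *N. winogradskyi* expressed its genes with its partner on ammonium, against growth alone on nitrite. Its own nirK cluster rose. Nwi_2648 (nirK) went from 38.5 ± 20.8 to 2891 ± 1223 CPM, a log2 fold change of 6.14 ± 0.66 (edgeR adjusted p = 0.00106), on 2, 1 and 1 counts in the single cultures and 149, 90 and 63 counts in the co-cultures. The ratio of the summed counts was 75.5 (95% exact interval for counting error 29.2 to 279). The adjacent genes Nwi_2651 (ncgA), Nwi_2652 (ncgB) and Nwi_2650 (ncgC), annotated with the nirK cluster, rose by 5.78 ± 0.78, 4.36 ± 0.54 and 3.66 ± 0.81. Nwi_2649, also annotated with the cluster, had 64 counts in the co-cultures against 2 in the single cultures, a ratio of 32 (95% exact interval 8.50 to 270), and passed at an edgeR adjusted p of 0.0130. Both of those counts were in single culture 1, and without it the log2 fold change was 7.50 against 4.79 with all libraries, a size that rests on counts of 0. It did not pass without co-culture 1, co-culture 3 or single culture 2 (adjusted p = 0.0914, 0.0509 and 0.0557) or with limma-voom (0.112), the highest of its 13 alternatives, where the lowest was 0.000217. Nwi_2652 also did not pass with limma-voom (0.112). Nwi_2650, at an edgeR adjusted p of 0.0474, lost its call with total-count scaling, with limma-voom and without co-culture 1, co-culture 3 or single culture 3. Without single culture 2 the log2 fold changes of Nwi_2650 and Nwi_2651 were 5.76 and 6.85. All co-culture libraries lay above all single-culture libraries for these 5 genes.

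The largest increases of all were in an adjacent pair. Nwi_0882, annotated as a class II aldolase/adducin domain protein, rose by 7.91 ± 0.71 (edgeR adjusted p = 0.000279), from 134 ± 92.2 to 33627 ± 6778 CPM, and Nwi_0883, annotated as 4-hydroxy-tetrahydrodipicolinate synthase, by 7.30 ± 0.56 (edgeR adjusted p = 0.000135). Nwi_2426, annotated as nicotinate-nucleotide pyrophosphorylase, rose by 4.63 ± 0.77 and Nwi_0742, annotated as a hemoglobin, by 3.90 ± 0.53. Nwi_2426 did not pass without co-culture 3 (adjusted p = 0.0512) or with limma-voom (0.0829), the highest of its alternatives, where the lowest was 1.32e-10, and its log2 fold change was 5.79 without single culture 1. The efflux and metal resistance list had 2 genes that rose and 13 that did not pass, with the same counts when adjusted over the list alone. Those that rose were Nwi_3130 (3.71 ± 0.50) and Nwi_3131 (3.55 ± 0.58), annotated as the CusB and CusA parts of a copper and silver efflux pump, and the list as a whole did not pass over all libraries (camera adjusted p = 0.0728). In fits chosen after seeing the data it passed without co-culture 1 (0.0195), co-culture 2 (0.0417), single culture 2 (0.0362) or single culture 3 (0.0211), and not without co-culture 3 (0.0929) or single culture 1 (0.188) or with an estimated correlation (0.596). Both kept their call whichever library was left out and lost it with limma-voom, and the log2 fold change of Nwi_3130 was 4.30 without single culture 2.

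Among the genes that fell, 4 adjacent loci included steps of sulfate assimilation, the route from sulfate to sulfide. Nwi_2764 (adenylylsulfate kinase) had -2.77 ± 0.63, Nwi_2763 (sulfate adenylyltransferase subunit) -2.67 ± 0.61, Nwi_2761 (phosphoadenosine phosphosulfate reductase) -2.42 ± 0.44 and Nwi_2762 (uroporphyrin-III C-methyltransferase, which makes a precursor of siroheme) -2.66 ± 0.60, with edgeR adjusted p from 0.0163 to 0.0484. Without single culture 1 the log2 fold changes were smaller for Nwi_2764 (-1.88), Nwi_2763 (-1.95) and Nwi_2762 (-1.98), still called. The translocase gene Nwi_1384 (secY, -2.76 ± 0.60), the histidine kinase gene Nwi_1138 (-2.03 ± 0.46) and the regulator gene Nwi_1988 (cbbR, -1.83 ± 0.41) also fell. All 7 decreases were lost when any co-culture library was left out, with adjusted p from 0.122 for Nwi_2761 to 0.294 for Nwi_1988, and with limma-voom. Leaving out single culture 3 ended all of them but Nwi_2761 (0.0596 to 0.150), and leaving out single culture 2 ended those of Nwi_1384, Nwi_1138 and Nwi_1988 (0.145 to 0.288). Nwi_1988 also lost its call with RLE scaling (0.0542) and without a filter (0.124), and Nwi_1138 without a filter (0.122) and after thinning (0.0538).

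**Figure D4:**
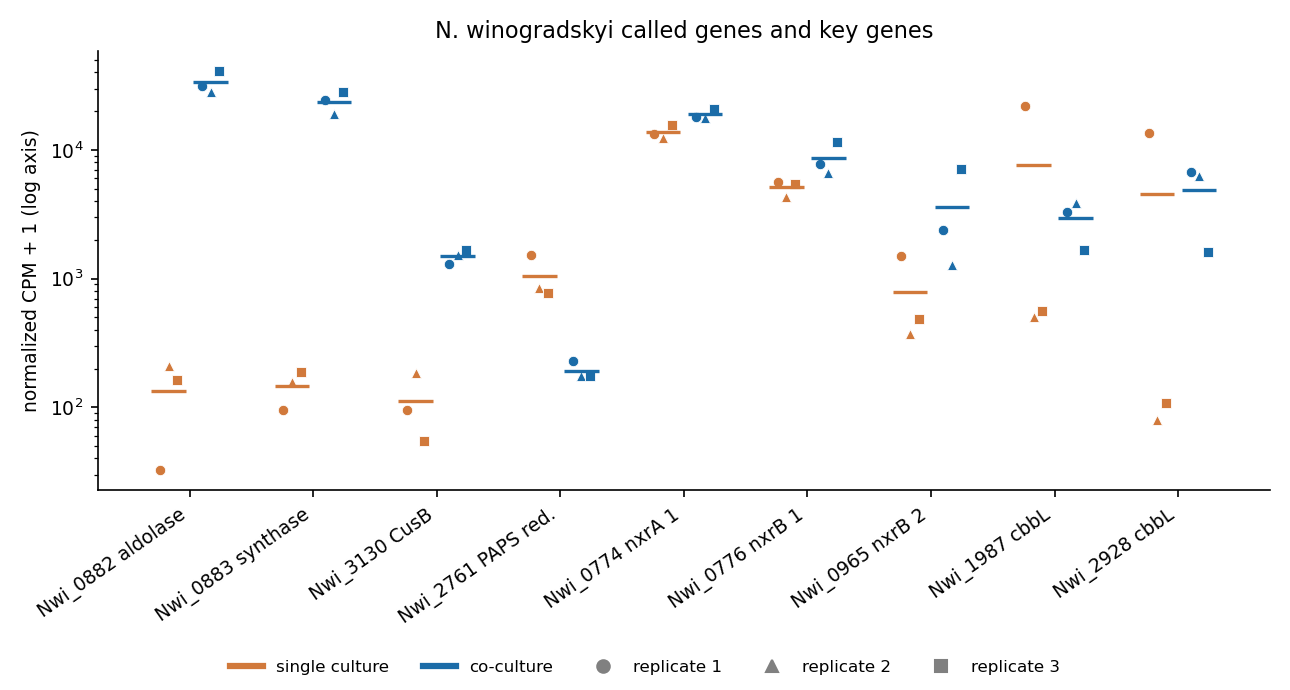
Normalized CPM plus 1 on a log axis for 9 *N. winogradskyi* genes, with 1 point per library, marker shapes for replicates and lines at the group means. Nwi_0882, Nwi_0883 and Nwi_3130 lie higher and Nwi_2761 lower in all 3 co-cultures, and single culture 1 (orange circles) lies far above single cultures 2 and 3 for the RuBisCO genes Nwi_1987 and Nwi_2928.

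Nitrite oxidation genes were not called. Of 8 tested members of that list, edgeR called 0, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. DESeq2 called 1 and limma-voom 0, and the camera adjusted p was 0.179. The nitrite oxidoreductase genes Nwi_0774 (copy 1, alpha subunit) and Nwi_0776 (copy 1, beta subunit) had 0.47 ± 0.37 and 0.77 ± 0.43, with every co-culture library above every single-culture library. Groups without overlap, in either direction, were found for 227 of the 948 *N. winogradskyi* genes tested (23.9%). Nwi_0965 (copy 2, beta subunit) had 2.19 ± 0.77 (edgeR adjusted p = 0.174), and passed without single culture 1 (adjusted p = 0.0170) and by DESeq2 (adjusted p = 0.0211), within a range of 0.0170 to 0.478 over its alternatives. The alpha subunit of that copy, Nwi_2068, had 1 to 17 counts per library and was not tested. The quorum sensing genes Nwi_0626 (autoinducer synthase) and Nwi_0627 (LuxR-family regulator) had -0.48 ± 0.56 and -1.54 ± 0.38 (edgeR adjusted p = 0.0573 for Nwi_0627, which passed without single culture 1 at 0.00491, the lowest of its alternatives, where the highest was 0.294). The sign of Nwi_0626 turned without single culture 3 (0.06). Of 4 tested members of the quorum sensing list, edgeR called 0 over all genes, and 2 fell when adjusted over the list alone. DESeq2 called 2 and limma-voom 0. The list did not pass (camera adjusted p = 0.159), within a range of 0.0213 to 0.596 over its alternatives. Among the RuBisCO large subunit genes, Nwi_1987 had 705, 19 and 21 counts in the single cultures and 116, 132 and 58 in the co-cultures, and Nwi_2928 had 433, 3 and 4 against 237, 217 and 55. Neither was called over all libraries, at -1.39 ± 1.20 and 0.10 ± 1.46. Without single culture 1 both were higher in co-culture, by 2.54 (edgeR adjusted p = 0.000767) and 5.74 (adjusted p = 0.000507). Those were the lowest adjusted p-values over their alternatives, where the highest were 0.866 and 0.997.

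Over all 948 *N. winogradskyi* genes tested, 21 were higher and 7 lower at an edgeR adjusted p under 0.05, and 156 had an unadjusted p under 0.05. With scaling by total counts 18 were higher and 19 lower, as that scaling moved the median log2 fold change by -0.17. Without single culture 1, which correlated with single culture 2 at 0.454 across genes on the log CPM scale against 0.918 for single cultures 2 and 3 (genes are not independent replicates), there were 199 calls, among them all 28 in the same direction. Without co-cultures 1, 2 and 3 there were 13, 16 and 12 calls. Of 23 lists tested, the nitrogen oxide metabolism list alone passed camera with its preset correlation (adjusted p = 0.000286, and adjusted p = 0.520 with an estimated correlation). Of its 5 tested members, 4 rose, all in the nirK cluster, and 1 did not pass, with the same counts when adjusted over the list alone.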

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

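Of the tests in this part, those on *N. winogradskyi* single culture 1 and the comparison of gene lists in *N. europaea* co-culture 3 were chosen after the result was seen.

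The nirK gene moved in opposite directions in the species. On the log2(CPM + 1) scale the co-culture mean minus the single-culture mean was -6.83 in *N. europaea* and 6.23 in *N. winogradskyi*, and for the nitrogen oxide metabolism lists it was -3.35 and 4.92. All 3 co-cultures lay on the same side of the single cultures in each species, and the difference between species was not tested. A candidate technical source is *N. europaea* reads counted on *N. winogradskyi* genes in the mixed libraries. Ribosomal protein genes, which such reads would also raise, had a median log2 fold change of 0.695 in *N. winogradskyi* (SD over 22 genes 0.74), between the bounds of 0.5 and 1 set for this test, and the same list had a median of 1.06 in *N. europaea*. By library the mean log2 CPM of these *N. winogradskyi* genes was 9.31, 9.80 and 8.04 in the co-cultures and 9.47, 8.32 and 8.42 in the single cultures. That source therefore cannot be told apart from a change in the cells, because the sequence similarity of the clusters was not measured here. Growth with a partner stays open as the biological explanation named by the design. For *N. winogradskyi* the partner came with ammonium in place of nitrite as the feed, and these cannot be told apart. Nitrite levels were not used here, so a change in nitrite cannot be told apart from the partner in either species.

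*N. winogradskyi* single culture 1 stood apart from single cultures 2 and 3. Counting noise is argued against by a chi-square per degree of freedom of 10.06 against single culture 2, and noise independent from gene to gene by a correlation of its log2 ratio between 459 neighbouring gene pairs of 0.457 (highest of 10000 shuffles of gene order 0.163). A mislabelled co-culture library was also weighed. Of the 199 genes called without this library, 167 were also tested with it, and over these its median position between single cultures 2 and 3 (0) and the co-cultures (1) was 0.634 (quartiles 0.141 and 1.13), above the bound of 0.5 set for that explanation, so this test alone goes with it. A library like the 3 co-cultures is argued against by the log CPM correlation across all 948 tested genes, chosen as a test after the position was known: it was at most 0.512 with a co-culture, below the 0.770 to 0.877 among co-cultures and no higher than the 0.549 that single cultures 2 and 3 reached. With single cultures 2 and 3 it was only 0.454 and 0.447, against 0.918 between them, so the library resembled neither group, and genes are not independent replicates. A culture in a different state, whatever its label, stays open, and no biological explanation was tested.

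*N. europaea* co-culture 3 stood apart from co-cultures 1 and 2, with 15.7% of its counts in the 10 most abundant genes against 28.7% and 29.7%. If fewer ammonia monooxygenase reads had only shifted the other genes by a common factor, scaling would leave them as close as in co-culture 2. The SD of their log2 ratio to co-culture 1 was 1.442 times that of co-culture 2, between the bounds set beforehand, so that test decided nothing. A common factor would move fixed gene lists alike, and as the whole explanation it is argued against by lists that moved apart: against co-cultures 1 and 2 the mean log2 ratio was 1.07 for 56 ribosomal protein genes (SD 0.58) and -0.35 for 89 iron uptake genes (SD 0.53), a difference of 1.42. These lists were picked after their means in that library were known, so the size of the difference is a selected one. Fewer such reads as a part of it stay open. A mislabelled single culture is argued against by a median position of 0.987 over 632 genes called without it and tested with it (single cultures 0, co-cultures 1 and 2 at 1), and independent noise by a neighbour correlation of 0.617 (highest shuffle 0.082). A different state of that culture stays open too, and no biological explanation was tested. In the *N. winogradskyi* counts co-culture 3 also lay further from co-cultures 1 and 2 (chi-square per degree of freedom 4.61 and 4.81) than these lay from each other (2.28).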

How the results depend on the processing

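The lists without pattern mismatches and the leave-one-out fits of the lists were chosen after seeing the data. Of the *N. europaea* count of 367, RLE scaling, total-count scaling, no filter, the mean of at least 50 counts, DESeq2, limma-voom and thinning gave 353 to 480 calls, an adjusted p under 0.01 gave 69, and leaving out a library gave 45 to 633. Thinning could change little, since the totals were already nearly equal. With 28 *N. winogradskyi* calls, the mean of at least 50 counts gave 11 (129 genes tested), DESeq2 77, limma-voom 11, an adjusted p under 0.01 gave 13, and leaving out a library gave 12 to 199. A stricter threshold lowers a count by construction, and a gene that is not tested cannot be called. Leaving out a library moved the counts in both directions. The cause of those moves and of the other higher counts was not tested. Of the 7 *N. europaea* lists and the 1 *N. winogradskyi* list, 0 passed camera with an estimated correlation (2 and 1 lists at an unadjusted p under 0.05), which gave the highest adjusted p of all 10 alternatives for each of them. With the preset correlation the highest was 0.000464 for ribosomal proteins, 0.00109 for nitrogen oxides and 0.00167 for NADH dehydrogenase. Leaving out a library gave 5 to 7 *N. europaea* lists and 2 to 6 *N. winogradskyi* lists, and RLE scaling gave 7 and 1. The lists without mismatches gave the same counts. There the called lists kept every tested member, so that setting could not test them. Same-numbered libraries correlated at -0.06, 0.14 and -0.09 in *N. europaea* and 0.11, -0.13 and 0.15 in *N. winogradskyi*, in their deviations from the group means. These values showed no pairing by number, but with so few libraries they cannot exclude one. With a replicate block there were 388 *N. europaea* and 15 *N. winogradskyi* gene calls. The latter were 14 higher and 1 lower (Nwi_2761), without Nwi_2650. Of the genes named for the size of their change and the key genes, 1 in *N. europaea* and 7 in *N. winogradskyi* lost their call. The block gave 6 *N. europaea* lists, without cytochromes c (camera adjusted p = 0.0743). It gave 3 *N. winogradskyi* lists, with efflux (0.0295) and ribosomal proteins (0.000914). Signs turned for genes that were not called: NE0945 (0.27 without co-culture 3, and -0.41 to 0.27 with a library left out), NE0943 (0.21 likewise, and -0.55 to 0.21), NE2064 (-0.0081 with total counts, -0.18 with limma-voom, -0.14 with the replicate block, -0.19 and -0.21 without co-cultures 1 and 2, and up to 0.47 without co-culture 3), NE1411 (0.020 without single culture 1, and down to -0.23), Nwi_1987 (0.57 with limma-voom, 0.79 with the replicate block, 2.54 without single culture 1, and down to -1.93 without single culture 2), Nwi_2928 (-0.089 with the mean of at least 50 counts, -0.19 and -0.03 without co-cultures 1 and 2, -0.47 and -0.45 without single cultures 2 and 3, and up to 5.74 without single culture 1) and Nwi_0626 (0.061 without single culture 3, and down to -0.81 without single culture 1). Counting the genes named for the size of their change and the key genes, without other list members, under each alternative that keeps all libraries, 186 *N. europaea* results kept direction and side of the threshold, 1 lost its call and 3 changed sign; in *N. winogradskyi* 138 kept both, 21 lost their call, 3 gained one and 3 changed sign. With a library left out these counts were 113, 26 lost and 5 changed in sign, and 89, 34 lost, 3 gained and 6 changed in sign. The cause was not tested. Keeping rRNA and tRNA genes was not run, since no counts for them were used here. The share of co-culture counts from *N. europaea* has no value under any setting because the deposited totals were nearly equal within each species. Few changes could be called in *N. winogradskyi*, where the median count was 5 per gene and 10% of simulated 2-fold changes were called. Depth was not separated there from the spread between libraries, since leaving out single culture 1 raised the calls from 28 to 199.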

Other observations

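The tests of gene order and the leave-one-out fits of lists in this part were chosen after the result was seen, as were the genes named here by locus outside the fixed rule. Called genes formed runs of neighbours. The longest run in *N. europaea* was 23 genes from NE0405 to NE0427, the main ribosomal protein cluster with NE0421 (secY) and NE0426 (rpoA), all higher, with a mean log2 fold change of 1.45. NE1764 to NE1771, 8 nuo genes, had a mean of 1.54, NE2045 to NE2051, 7 genes with rpoB, rpoC and ribosomal proteins, 1.40, and NE0680 to NE0684 (5 genes with nor/coxA2) 1.57. NE1009 to NE1013, 5 genes that include ctaB, a SURF1 family gene and coxC, had a mean of 1.65. Besides the downward runs of the nirK cluster and of the sulfate assimilation genes, some held genes without a named function. NE2151, NE2152 and NE2153, annotated as hypothetical, fell by log2 values of -4.28 ± 0.47, -3.58 ± 0.47 and -2.49 ± 0.31 (edgeR adjusted p from 0.00214 to 0.00489), beside NE2150 (trpE), and NE0724 and NE0725 fell by -2.57 ± 0.16 and -3.52 ± 0.31. In *N. winogradskyi* the run Nwi_3128 to Nwi_3131, which ends with the copper efflux genes, had a mean of 3.68, and Nwi_2427, which has no product name and lies beside Nwi_2426, rose by 4.71 ± 0.53. A hypothesis is that neighbouring genes change together, as in operons. Calls that fall independently of gene order are argued against by the number of neighbouring pairs both called, which was 134 in *N. europaea* (highest of 10000 shuffles 79) and 14 in *N. winogradskyi* (highest 4). Operons were not used here, so a link to them was not tested, and counts of called genes are not counts of independent events.

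Other lists went several ways. In *N. europaea* oxidative stress defence (camera adjusted p = 0.434) 5 genes rose and 3 fell, with the thioredoxin gene NE2328 at 1.73 ± 0.22 and the superoxide dismutase gene NE0870 (sodB) at -1.21 ± 0.18. The members counted there also include ferredoxins, which the pattern caught by name. In the Calvin cycle list 3 genes fell, among them NE1920 (cbbS, -1.48 ± 0.37), and 1 rose, NE1926 (carbonic anhydrase, 0.91 ± 0.20), with a camera adjusted p of 0.726 and a mean of -0.20 beside a median of 0.08. The cytochrome oxidase list had a mean of -0.48 and a median of 0.52, since it also held NE0924 and NE0927 (camera adjusted p = 0.872). The other *N. europaea* lists did not pass over all libraries, with camera adjusted p from 0.245 for DNA replication to 0.920 for secretion and pili. Aminoacyl-tRNA synthetases passed downward without co-culture 3 (0.0339), and the highest value over their alternatives was 0.980. Among these other lists, motility had 1 gene that fell of 54 tested (camera adjusted p = 0.434). Efflux had 3 that rose and 3 that fell of 48 (0.867), with a mean of 0.04 that total-count scaling turned to -0.06. The Calvin cycle median turned to -0.01 with that scaling. In *N. winogradskyi*, ribosomal proteins (median 0.69) and chaperones (median 0.50) each had a camera adjusted p of 0.0728, and efflux the same. Ribosomal proteins passed without co-culture 3 (0.000538) or single culture 1 (0.0465), and chaperones without co-culture 1 (0.0472) or single culture 1 (0.00249). Ribosomal proteins did not pass without co-culture 1 (0.531) or 2 (0.559). Their voom-scale mean was -0.04 and -0.12 there, against 0.45 with all libraries. With the preset correlation the highest camera adjusted p for chaperones was 0.491. With an estimated correlation it was 0.601 for ribosomal proteins and 0.596 for chaperones. Motility (0.422) had 0 genes called by edgeR of 13 tested, 2 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma-voom, and its mean of 0.19 turned to -0.0070 with total-count scaling. The Calvin cycle list had 1 gene that fell of 10 (0.770), with a mean of -0.47 and a median of -0.92 where camera gave an upward direction. Single culture 1 weighed on both: its mean log2 CPM was 6.57 against 9.30 and 9.67 in single cultures 2 and 3 for motility, and 11.32 against 8.03 and 8.65 for the Calvin cycle. Without it the mean log2 fold change on the voom scale went from 0.51 to -0.11 for motility and from 0.53 to 1.46 for the Calvin cycle, again without a call (camera adjusted p = 0.943 and 0.129).

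Single culture 1 of *N. winogradskyi* held high counts in more than the RuBisCO genes. The carboxysome shell gene Nwi_1985 had 769 counts in it against 21 and 14 in single cultures 2 and 3. The RuBisCO small subunit genes Nwi_1986 and Nwi_2929 had 213 and 894 against 0 to 7. In the co-cultures Nwi_1985 had 211, 141 and 34 counts, Nwi_1986 had 35, 17 and 14, and Nwi_2929 had 717, 600 and 293. Each of these genes thus had fewer counts in single cultures 2 and 3 than in any co-culture. Nwi_0459 and Nwi_0457, the latter annotated as part of a nitrate, sulfonate or bicarbonate transporter, had 264 and 159 counts against 11 to 18 in the other single cultures and 0 to 3 in the co-cultures.

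There are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. For *N. europaea* genes the real split gave 367 calls and the highest other 0, and 1 of 10 splits reached the real count; for its lists the real split gave 7 and the highest other 6, again 1 of 10. For *N. winogradskyi* genes the real split gave 28 and the highest other 0, with 1 of 10 at that count. For its lists the real split gave 1 and the highest other 5, and 9 of the 10 splits had at least 1; the splits with 5 put single culture 1 with co-culture 1 and another co-culture, which points to a structure of the samples.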
